A study of Homo sapiens with 2 samples.

How the data were processed

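Total RNA of TSU-Pr1 bladder carcinoma cells, called K12 cells in the labels, was sequenced on a BGISEQ-500 instrument, per the series design text. Cells were grown with 8% serum and harvested 48 h after transfection with siCtrl or siCINP. There was 1 library in each group. The siRNA sequences are not given in the sources used here.

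The authors deposited 1 table per library with a gene identifier, transcript identifiers, a length, an expected count and an FPKM value for each gene with reads, per the file headers. The expected counts deposited by the authors are estimated reads per gene, need not be whole, and are not normalised. The FPKM values deposited by the authors are expression values scaled for gene length and library total, per the file headers. The submitters' processing notes name Bowtie2, HISAT and the build hg19, with no versions. The counting tool, the annotation and any strand setting are not given in the sources used here. Expected counts that are not whole within 0.005 were taken as a sign that reads were shared between genes, which was not checked. Whole counts were present for 63.3% of the listed genes in siCtrl and 63.1% in siCINP. FPKM values of genes with over 300 reads imply totals of 10577240 and 10524907 reads, above the summed expected counts of 10365249 and 10314147, with 50 bases subtracted from the length in that calculation. The 10 most abundant genes took 4.87% of reads in siCtrl and 4.39% in siCINP.

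Of 19052 gene identifiers in either table, 18971 matched a symbol in a reference table of the GRCh38 assembly and 81 did not. Since that build differs from the one in the notes, no coordinates are given, and the reference served only for names and, from GENCODE 29, transcript sequences. A gene's 3' UTR was the longest annotated one among its protein-coding transcripts in the basic set.

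Expected counts were rounded to whole numbers. Libraries were scaled by the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 0.974 for siCtrl and 1.03 for siCINP. The value of a gene was the log2 ratio of siCINP over siCtrl, with an exact Clopper-Pearson 95% interval on the split of its reads between the libraries, computed with scipy 1.17.1. A count of 0 stood at 3 reads, which is 0.289 CPM in siCtrl and 0.291 in siCINP, while its interval used the count of 0. Genes with 20 or more reads in at least 1 library were compared. A gene passed the size rule with a log2 ratio of 1 or more in either direction and an interval that excluded 0. This is a rule of size, not a test of the conditions.

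The 28 gene lists, the size rule, the minimum of reads, the rule for named genes and most of the other settings tried were fixed before the data were examined. Named genes are CINP and KLF5, the 12 genes in each direction whose interval end nearest 0 lay farthest from it among those passing the size rule, and up to 4 members of each list by the same measure. Some genes selected by these rules are not reported here. For each list with 5 or more compared members the median log2 ratio was placed among 10000 random lists of the same size, matched on 20 bins of mean expression, and the list was said to stand apart below the 2.5th or above the 97.5th percentile. This describes these libraries. Some genes are in several lists. The reported KLF5 targets and CINP partners were listed from general knowledge.

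Settings varied were total-count, upper quartile and DESeq2 1.42.0 median-of-ratios scaling, the deposited FPKM with 2 pseudocounts, thinning of the deeper library, other minimums of reads, other size rules, the mean in place of the median, other matching, and lists without their most extreme member. Settings added after seeing the data were whole-count genes only and the removal of genes with particular 3' UTR heptamers, once with 2 and once with 4 heptamers.

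For the heptamer scan, log2 ratios of 11671 compared genes with a 3' UTR of 30 or more bases were adjusted by linear regression for 3' UTR length, GC content and expression and limited to 1.5 in either direction. The mean of these residuals was taken for each of 16349 heptamers present in 30 or more genes, and 100 permutations of the residuals over genes gave the range without any relation. The scan was repeated with length and dinucleotide shares of the 3' UTR and of the coding sequence in the regression. Both forms were chosen after seeing the data.

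The methods were tested on simulated data for this comparison. With counts drawn for 19052 genes, the size rule recovered 99 of 100 genes changed by a log2 fold of 2.0 and 99 of 100 changed by 1.5, and called 35 of 12802 unchanged genes. The intervals held the true ratio for 95.0% of unchanged genes. Of 200 unchanged lists of 30 genes among 13001, 3.5% stood apart, and of 100 lists raised by 0.3 all 100 did. For the scan, the measured residuals of 11671 genes were permuted, and 20 of 20 planted heptamers ranked lowest. All were heptamers of moderate frequency, planted at a single size close to the mean residual of the lowest heptamer found. Smaller shifts and rarer heptamers were not tried. The simulated counts of the other steps hold counting error only, not differences between cultures.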

Results

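Transcript levels were measured by sequencing of total RNA from TSU-Pr1 cells, a human bladder carcinoma line that the series title describes as carrying stable KLF5 expression. KLF5 is a zinc-finger transcription factor of epithelial cells. Cells were transfected with a control siRNA (siCtrl) or with siRNA against CINP (siCINP), which encodes a protein known to bind cyclin-dependent kinase 2, and RNA was taken 48 h later. There was 1 library in each of the 2 groups. The siCtrl library held 10365249 reads over 17847 listed genes and the siCINP library 10314147 reads over 18115 genes. With 1 library per group, no difference below has a replicate check and no p-value is given. Every interval compares these 2 libraries, not the conditions, and covers counting error only. A gene with 20 reads in each library had an interval of 0.97 on either side of its log2 ratio, and one with 1000 reads an interval of 0.13.

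The comparison of siCINP with siCtrl asked which transcripts differ when CINP is depleted. CINP itself (gene 51550) had 203 reads in siCtrl and 53 in siCINP, a 4.02-fold lower level (log2 ratio -2.01, 95% interval -2.47 to -1.56). Its deposited FPKM was 20.6 in siCtrl and 5.27 in siCINP. KLF5 (gene 688) had 4013 and 4077 reads, a log2 ratio of -0.05 with an interval of -0.11 to 0.02, so no difference was detectable at this depth. The files do not separate reads of the stable KLF5 construct from those of the endogenous gene, and the annotated KLF5 3' UTR holds the heptamer GCAAGAA described below.

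Of 13076 genes with 20 or more reads in at least 1 library, 221 were at least 2-fold higher in siCINP and 184 at least 2-fold lower, each with an interval that excluded 0. Most genes differed little: 88.0% lay within 1.5-fold, and the quartiles of the log2 ratio were -0.21 and 0.20. Over all 13076 compared genes, intervals lay above 0 in 2430 and below 0 in 3023. The counts of intervals in the gene lists below are to be read against these. By the mean reads of both libraries, the median was 29 for the higher genes, 113.75 for the lower genes and 329 for all compared genes. Scaling to total counts gave 296 higher and 149 lower genes, which moved the share of higher calls from 54.6% to 66.5%. The share was 38.75% with a minimum of 100 reads and 45.1% with an interval wholly beyond 2-fold, so the balance depended on the settings. Fractional expected counts, taken as the mark of reads shared between genes, were present in 102 of the 221 higher and 89 of the 184 lower genes. Of all 13076 compared genes, 5223 had them. Of the lower genes with an annotated 3' UTR, 75 of 156 (48.1%) carried the heptamer TGCAAGA or GCAAGAA there, compared with 2150 of 11713 compared genes (18.4%) and 20 of 178 higher genes (11.2%). The heptamers TCGGAGA or CGGAGAA were carried by 17 of 178 higher genes (9.55%), 492 of 11713 compared genes (4.20%) and 7 of 156 lower genes (4.49%). Both pairs of heptamers were singled out after the values were seen.

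**Figure D1:**
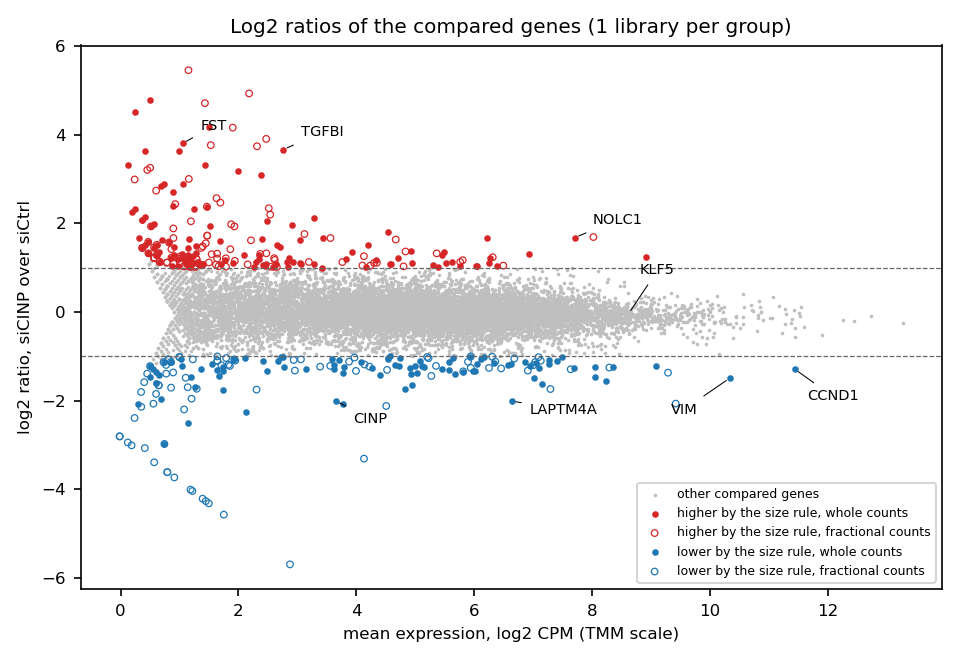
Log2 ratio of siCINP over siCtrl against mean expression in log2 CPM for the 13076 compared genes, 1 library per group. Red and blue points are the 221 higher and 184 lower genes, open where expected counts were fractional, and dashed lines mark the 2-fold rule. CINP lies at -2.01 and KLF5 at -0.05.

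The 12 higher genes that led the fixed ranking by the interval end nearest 0 included RAB4B-EGLN2, FST, LIMS4, GOLGA6L22, TNS4, PLGLB1, KRT6A, KRT5, TGFBI, ZHX1-C8orf76 and PKP1. Only 3 of the 12 had whole expected counts in both libraries. FST, which encodes the activin antagonist follistatin, had 0 reads in siCtrl and 44 in siCINP, with the lower end of the interval at a log2 ratio of 3.45. TGFBI, a secreted matrix protein, had 10 and 133 reads (12.7-fold higher), and PKP1, a desmosomal plaque protein, had 3 and 57 reads (18.1-fold higher). KRT5 and KRT6A, keratins of basal and stratified epithelium, had 4 and 75 reads and 2 and 55 reads. Their counts were fractional, but the sum over both was 6 reads in siCtrl and 130 in siCINP (log2 ratio 4.37, 3.21 to 5.84), with KRT6B and KRT6C not among the listed genes. TNS4 had 7 and 110 reads, with fractional counts. The values of RAB4B-EGLN2, LIMS4, GOLGA6L22, PLGLB1 and ZHX1-C8orf76 are uncertain, since these genes share sequence with neighbouring or copied genes. RAB4B-EGLN2 had 0 and 96 reads, while EGLN2 and RAB4B, which it joins, had 489 and 511 and 62 and 64 reads.

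All 12 of the lowest-ranked genes had fractional counts and are uncertain: EIF3CL, PEDS1-UBE2V1, LOC100132287, FSBP, ARPIN-AP3S2, PLGLB2, LIMS3, RPS10-NUDT3, RNU6-2, RNU6-9, PVRIG2P and GTF2IP1. EIF3CL had 148 reads in siCtrl and 0 in siCINP, but its near-identical copy EIF3C had 11389 and 12730, and their sum had a log2 ratio of 0.07 (0.04 to 0.11). LIMS3 had 46 and 0 reads where LIMS4 had 1 and 46, and their sum was 47 in siCtrl and 46 in siCINP. PLGLB2 had 47 and 0 reads where PLGLB1 had 0 and 29, and their sum had a log2 ratio of -0.765 (-1.485 to -0.067). That sum was lower in siCINP, unlike the sum of LIMS3 and LIMS4.

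The same ranking among genes with whole expected counts, chosen after seeing the data, gave a different set of lower genes. LAPTM4A, a lysosomal membrane protein, had 1611 reads in siCtrl and 420 in siCINP (4.02-fold lower), and KLHL15, a substrate adaptor of a ubiquitin ligase, had 224 and 56 (4.19-fold lower). LMNB1, which encodes lamin B1, was 3.08-fold lower, with 2171 and 740 reads. VIM, the intermediate filament protein vimentin, had 19204 and 7167 reads (2.81-fold lower, log2 ratio -1.49, -1.53 to -1.45). VIM-AS1, which overlaps VIM on the other strand, had 4560 and 1624 reads and is uncertain, as no strand setting is given in the sources used here. TMEM64, HDDC2, EIF2S2 and LYPLA1 were 3.35-fold, 3.15-fold, 2.77-fold and 2.82-fold lower. BEAN1 had 73 and 16 reads. Of the 12 lower genes in this ranking, with CINP among them, 8 carried TGCAAGA or GCAAGAA in the 3' UTR: LAPTM4A, KLHL15, LMNB1, TMEM64, VIM, HDDC2, EIF2S2 and LYPLA1. The higher genes in this ranking, beyond FST, TGFBI and PKP1, included LAD1 (1 and 29 reads), MAL2 (8 and 76), OAS2 (5 and 52), SLC43A3 (3 and 39), EHF (1 and 24), C1orf116 (2 and 26), COL17A1 (37 and 168) and NOLC1 (1001 and 3365). NOLC1, a nucleolar phosphoprotein 3.21-fold higher in siCINP, carried TCGGAGA or CGGAGAA, and LAD1, SLC43A3, EHF and C1orf116 carried TGCAAGA or GCAAGAA although they were higher.

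The median of 44 G2/M and mitosis genes was -0.30, below all 10000 expression-matched random lists, although none passed the 2-fold rule. In 38 of the 44 the interval lay below 0 and in 0 above it. CDC25C, a phosphatase that activates CDK1, had 324 reads in siCtrl and 178 in siCINP (log2 ratio -0.93), and KIF23, ESPL1 and CDCA3 had log2 ratios of -0.70, -0.71 and -0.70. CDC25C and KIF23 carry TGCAAGA. The 44 DNA replication genes had a median of -0.04, at the 45.8th percentile. Within that list FEN1, a flap endonuclease that carries GCAAGAA, was at -0.73 and RFC2, a clamp loader subunit, at 0.41. The ATR-CHK1 checkpoint list had a median of 0.02 over 28 genes (78.8th percentile), with CDC25B at -0.61 and ETAA1 at 0.68, and ETAA1 carries TCGGAGA or CGGAGAA. The 14 genes listed as CINP partners had a median of -0.06 (33.3rd percentile), with RAD9A at -0.43 and CCNE1 at 0.40. The 20 CDK inhibitors and G1 cyclins had a median of -0.01 (62.6th percentile), and 4 of them were at least 2-fold lower. CCND1, which encodes cyclin D1, had 39833 and 17042 reads (log2 ratio -1.29, -1.32 to -1.27), CDKN1A, the CDK inhibitor p21, had 2103 and 1038, CDK6 had 1066 and 555 and CDKN2D had 81 and 34. The mean of that list was -0.23, at the 0.67th percentile, so mean and median differ in whether it stands apart. CDK6 had fractional counts and carries heptamers of both pairs.

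The p53 target list had a median of -0.23 over 29 genes (0.06th percentile). Of these, 15 intervals lay below 0 and 1 above. GDF15, a secreted stress cytokine, had 749 and 296 reads (log2 ratio -1.41), TP53INP1 was at -1.24, and XPC, a DNA damage sensor, was higher at 0.88. The 26 reported KLF5 targets had a median of -0.25 (0.01st percentile), with 3 members at least 2-fold lower and 2 at least 2-fold higher. The list was not sorted by the direction in which KLF5 is reported to act, so its median is no measure of KLF5 activity. PDGFA, a growth factor chain, was at -1.26 and CCND1 is in this list too, while KRT5 and LAMA3, a laminin chain of the epidermal basement membrane with 105 and 384 reads, were higher. The mean of this list was -0.05, at the 38.5th percentile, so its place below the random lists was not kept with the mean. The 16 KLF and SP factors had a median of -0.09 (22.2nd percentile), with KLF6 at -0.48 and KLF7 at 0.46, both carrying TGCAAGA.

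The 34 interferon-stimulated genes had a median of 0.66, above all 10000 random lists. Of these, 11 were at least 2-fold higher and 0 at least 2-fold lower, and 24 intervals lay above 0 and 0 below. OAS2 had 5 reads in siCtrl and 52 in siCINP (9.92-fold higher), MX1 had 5 and 42, OASL had 9 and 56 and IFIT2 had 31 and 127. These genes encode antiviral effectors, and MX1 and OASL had fractional counts. Inflammatory cytokines had a median of -0.04 over 20 genes (28.0th percentile), with BIRC3 at -1.20, NFKBIZ at -0.86, CXCL8 at -0.80 and CCL5 at 0.75. CXCL8 carries TGCAAGA, and the other 3 had fractional counts. Immediate early genes had a median of 0.00 over 31 genes (62.3rd percentile), with SPRY4 at -0.61 and FOSB at 0.94, and FOSB carries TCGGAGA or CGGAGAA.

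The 18 basal and squamous markers had a median of 0.61, above all 10000 random lists, with 8 at least 2-fold higher and 0 at least 2-fold lower, and with 9 intervals above 0 and 5 below. Over all 18 the reads summed to 30465 in siCtrl and 29292 in siCINP. COL17A1, a hemidesmosomal collagen, had 37 and 168 reads and LAMA3 105 and 384. The 8 higher members had at most 105 reads in siCtrl, and 5 of the 8 had fractional counts. The median depended on these low-abundance members: with a minimum of 100 reads it was -0.04 over 11 members (48.0th percentile), and with whole counts only it was 0.11 (92.3rd percentile). Epithelial markers had a median of 0.06 over 19 genes (77.0th percentile), with CLDN7 at 2.07, KRT7 at 0.88, DSP at 0.60 and CLDN1 at -0.59, where KRT7 had fractional counts. Of epithelial genes outside the basal list with under 50 reads in siCtrl and 5 or more over both libraries, a minimum used only here, 10 of 18 had a log2 ratio above 0, and their reads summed to 293 in siCtrl and 372 in siCINP. Mesenchymal and matrix genes had a median of -0.10 over 28 genes (12.9th percentile). VIM was lower, TGFBI was higher, and THBS1, which carries TGCAAGA, was at -0.60.

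**Figure D2:**
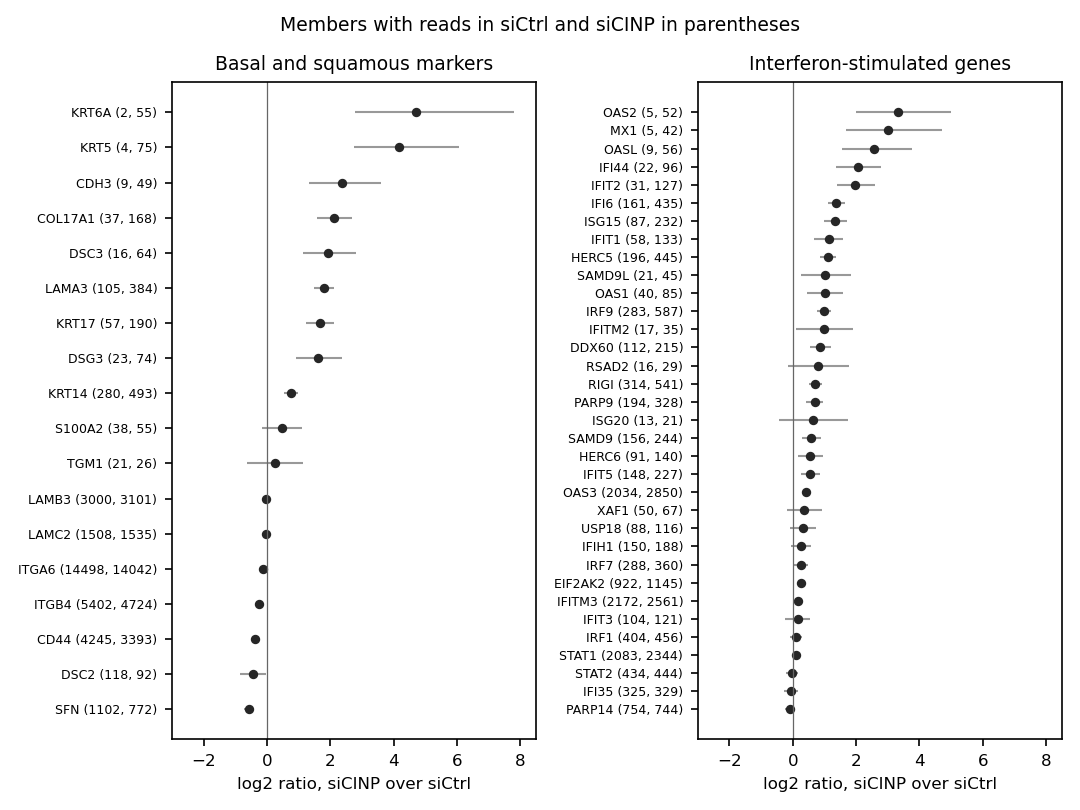
Log2 ratio of siCINP over siCtrl for each compared member of the basal and squamous list (left) and the interferon-stimulated list (right), with 95% counting intervals as lines and reads in siCtrl and siCINP in parentheses. Members with the largest ratios, such as KRT6A and OAS2, had few reads in siCtrl.

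Ribosome biogenesis genes had a median of 0.11 over 50 genes (99.99th percentile), with 23 intervals above 0 and 8 below. NOLC1 passed the 2-fold rule, and PPAN, DKC1 and POLR1B were at 0.96, 0.68 and 0.64, all 3 with fractional counts. Ribosomal proteins had a median of -0.13 over 78 genes (6.92nd percentile), where the matched random lists centred at -0.08. Here 62 intervals lay below 0 and 3 above, but these narrow intervals leave out scaling error. With total scaling the list median was -0.05. RPS24 was at -2.07 (11127 and 2786 reads, fractional counts), while RPS12, RPL3 and RPL22 were at -0.90, -0.72 and -0.47. Hypoxia and glycolysis genes had a median of -0.33 over 30 genes, below all 10000 random lists. SLC2A1, the glucose transporter GLUT1, was at -1.14, BNIP3 at -0.89, LDHA at -0.52 and PDK1 at -0.58, and SLC2A1 and PDK1 carry TGCAAGA. The integrated stress response list had a median of -0.21 over 27 genes (0.21st percentile), with CHAC1, a glutathione-degrading enzyme, at -1.23 and STC2 at -0.82. The unfolded protein response list had a median of -0.20 over 24 genes (0.51st percentile), with the chaperones DNAJB11 at -0.62 and CANX at -0.47, both carrying TGCAAGA, and HSPA5 at -0.41 with fractional counts. Apoptosis regulators had a median of -0.17 over 29 genes (0.92nd percentile), with BIRC3 at -1.20, BMF at -1.96 and XIAP at -0.75. BIRC3 and XIAP had fractional counts, and XIAP carries TGCAAGA or GCAAGAA. The apoptosis list no longer stood apart with no minimum of reads (median -0.07, 23.2nd percentile), with the mean (-0.17, 2.55th percentile) or without its most extreme member (median -0.10, 9.16th percentile).

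The remaining lists did not stand apart by the median with the main settings. Mitochondrial translation and OXPHOS genes had a median of -0.08 over 37 genes (17.8th percentile), with SDHA at -0.85 and fractional counts. Cholesterol synthesis genes had a median of 0.01 over 25 genes (86.0th percentile). Replication-dependent histones had a median of 0.20 over 8 genes (76.1st percentile), while 20 of the 28 listed had under 20 reads, so most were not compared. H2AC11 was at -1.36 (22 and 9 reads, -2.66 to -0.18), H3C4 at 1.22 (9 and 22 reads, 0.05 to 2.52) and H2BC5 at 0.62. H3C4 and H2BC5 had fractional counts. The RNA interference machinery had a median of -0.18 over 14 genes (2.61st percentile), just inside the limit, but stood apart with upper quartile scaling (2.31st percentile) and with the mean (0.64th percentile). Its members included TNRC6A at -0.93, AGO2 at -0.64 and DROSHA at 0.65, and TNRC6A and AGO2 carry TGCAAGA or GCAAGAA. Housekeeping genes had a median of -0.08 over 25 genes (40.5th percentile), with GAPDH at -0.21 and REEP5 at 0.57, the latter with fractional counts and TCGGAGA or CGGAGAA. Endothelial markers had a median of 0.37 over 5 genes (91.0th percentile), with ENG, which carries heptamers of both pairs, at -0.32 and PECAM1 at 0.69 with fractional counts. Leukocyte markers had 3 compared members, among them ITGAM with 16 and 22 reads and CD68 with 107 and 125. The liver, prostate and red cell markers also had too few compared members for a median. In all, 10 of the 26 lists with 5 or more compared members stood apart, 3 above and 7 below. By chance, 1.3 would be expected to do so if the genes within a list varied independently. Genes of a list can vary together between cultures, so 10 against 1.3 does not show more than such variation.

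**Figure D3:**
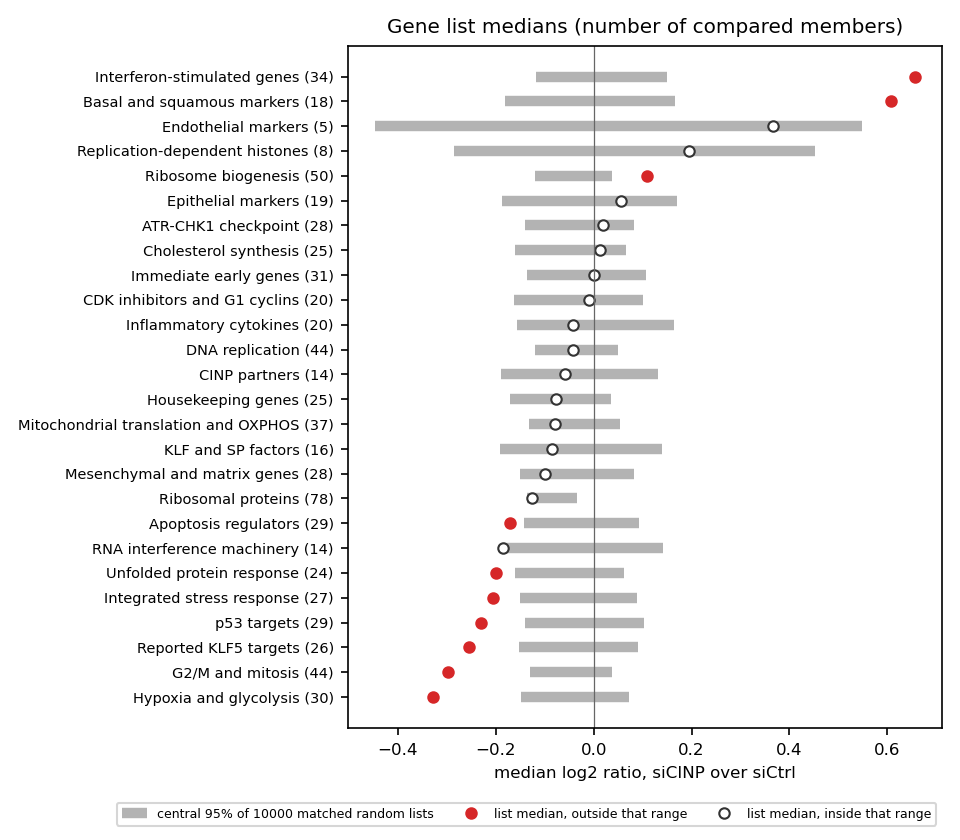
Median log2 ratio of siCINP over siCtrl for the 26 lists with 5 or more compared members, against the central 95% of 10000 random lists matched on expression (grey bars). Filled points lie outside that range, from -0.33 for hypoxia and glycolysis to 0.66 for interferon-stimulated genes.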

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

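The whole-count and heptamer alternatives were chosen after seeing the data, and the rest were planned. The CINP log2 ratio lay between -2.01 and -1.78 in its 6 alternatives. Of 804 alternative values of 134 other genes selected for naming, 704 stayed inside the gene's counting interval, 100 moved outside it, and 0 changed sign where the interval had excluded 0. Of 383 alternative list medians, 361 kept their side of the percentile limits and moved by no more than the distance from the middle to the edge of the central range of the random lists, and 16 of 26 lists did so throughout.

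The counts of higher and lower genes moved by over 1.5 times, by construction, with the 1.5-fold rule (662 and 637), an interval wholly beyond 2-fold (60 and 73), a minimum of 100 reads (62 and 98) and whole counts only (119 and 95). Lower genes without carriers of any of the 4 heptamers were 107. The counts were 83 and 72 with log2(FPKM + 1), which shrinks low genes. With no minimum of reads 339 genes were higher.

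Among lists, basal and squamous markers changed most: -0.0425 with a minimum of 100 reads, against 0.11 with whole counts, 1.11 with the mean, 1.18 without carriers of 2 heptamers and 1.62 without carriers of 4. Interferon-stimulated genes were at 0.48 with log2(FPKM + 1), 0.48 with a minimum of 100 reads and 0.87 with the mean. Apoptosis regulators were at -0.0681 with no minimum, -0.17 with the mean, -0.10 without the most extreme member and -0.29 with whole counts. Means were -0.23 for CDK inhibitors and G1 cyclins, -0.0501 for reported KLF5 targets and -0.26 for RNA interference machinery, which was at -0.14 with upper quartile scaling. Ribosomal proteins were at -0.0505 with total scaling and at -0.0504 with log2(FPKM + 1) and with log2(FPKM + 0.1). Hypoxia and glycolysis genes were at -0.19 with log2(FPKM + 1), mesenchymal and matrix genes at 0.0288 with no minimum, and ATR-CHK1 checkpoint genes at -0.10 with whole counts. Beyond what an alternative removes by construction, the cause was not tested. Histones had too few members with a minimum of 100 reads or whole counts, and endothelial markers in those, without the most extreme member and without heptamer carriers. Depth limits the low-abundance genes, since 20 reads in each library leave an interval of 0.97 on either side.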

Other observations

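The heptamer scan, both composition tests, the tests on TCGGAGA in the lists, the test on near-floor epithelial genes and the test on VIM were chosen only after the results were seen. The bound for the epithelial test was also reset after its value was known, so that less is excluded, as were the explanation and bound of the TCGGAGA tests, and the composition tests and the test on VIM replaced earlier forms whose values were known and whose outcome did not depend on the explanation. The tests on CINP transcripts, on site position and on interferon transcripts were written down before their results were seen.

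Genes with TGCAAGA in the 3' UTR were lower in siCINP: among 16349 heptamers it ranked lowest (z -14.5, against -4.73 for the lowest of 100 permutations), with a mean residual of -0.1543 over 1310 genes (SE 0.0121), and GCAAGAA, shifted by 1 base, ranked next at -0.146. Length or base composition of the transcript is argued against as the whole cause, as far as a linear fit removes it: after adjusting for length and dinucleotide content of 3' UTR and coding sequence, which gave fitted log2 ratios with an SD of 0.101 over genes, the mean was -0.1495 (SE 0.0119, z -14.3, against -4.78 for the lowest heptamer in 100 permutations). The residual with the site in the 3' UTR minus that with the site in the coding sequence only was -0.1482. A candidate explanation is seed pairing of the siRNA used against CINP, in the manner of a microRNA, since 8 of 9 annotated CINP transcripts hold TGCAAGA. They are transcripts of 1 gene with 1 site each, so they count as 1 observation and are weak support. For comparison, 27.2% of genes hold TGCAAGA somewhere in their chosen transcript. The 3' UTR used for CINP holds neither TGCAAGA nor GCAAGAA. The siRNA sequence is not given in the sources used here, so it stays a hypothesis that part of the lower genes may reflect the reagent and not CINP. VIM holds only the shifted GCAAGAA, and genes with GCAAGAA but without TGCAAGA in the 3' UTR had a weaker mean residual of -0.0927. At the other end of the scan, genes with TCGGAGA were higher in siCINP (mean residual 0.1695, SE 0.028), and the same adjustment left 0.1743 (z 7.40, against 4.77 for the highest heptamer in permutations), which argues against composition as the whole cause here too. With TCGGAGA in the coding sequence only, the mean residual was 0.121 over 865 genes (SE 0.0131), against -0.0161 (SE 0.0037) with no site. For TGCAAGA, genes with a coding site only were at -0.0061 (SE 0.0092), against 0.0232 (SE 0.0040) with no site. Coding-only genes thus differed from genes with no site for both heptamers, but for TGCAAGA by far less than genes with a 3' UTR site. Values by site position were not adjusted for length or composition of the coding sequence. A relation with the coding site itself was therefore not tested. A site of the control siRNA was not tested.

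Low-abundance basal and squamous markers were higher in siCINP, with 8 of 18 members, picked for being at least 2-fold higher, going from 253 to 1059 reads in sum. The 18 together went from 30465 to 29292, so the list as a whole did not gain reads, and with a minimum of 100 reads it lay at the 48.0th percentile. Loss of pairing at TCGGAGA is argued against as the direct cause for most of the 8, since 0% of them carry TCGGAGA in the 3' UTR (0 of 8, upper 95% bound 36.9%, against 2.19% of compared genes) and 0 hold it anywhere in the chosen transcript. The control siRNA itself is not excluded, since its sequence is not given in the sources used here. Dilution by other cells is argued against as the cause of the lower VIM, since 23 other mesenchymal and matrix genes with 100 or more reads in siCtrl had a median log2 ratio of -0.1074 (SD 0.412) and a lowest of -0.68, against -1.49 for VIM. Cells or reads of a basal epithelial type in the siCINP library cannot be told apart from a change within the cells: other epithelial genes near the floor had a median of 0.4405, at the 96.2nd percentile of matched lists, with 10 of 18 higher, and near-floor genes cannot exclude a small share. A response to CINP depletion stays open and untested, since the 1 library per group confounds it with culture and reagent.

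Interferon-stimulated genes were higher in siCINP, with 11 of 34 members, picked for being at least 2-fold higher, going from 635 to 1748 reads in sum, and all 34 from 11787 to 15840. Loss of pairing at TCGGAGA in the 3' UTR is argued against for most of the 11, since 0% of them carry it there (0 of 11, upper 95% bound 28.5%). However, 3 of the 11 hold it somewhere in the chosen transcript, against 11.1% of genes. Genes with a coding site only had a mean residual of 0.121, not adjusted for composition of the coding sequence. A part through coding sites is therefore not excluded for those 3, and neither are other sites of the control siRNA. A response to double-stranded RNA with release of interferon cannot be told apart from other causes, as IFNB1, IFNL1, IFNL2 and IFNL3 summed to 1 read in siCINP and 0 in siCtrl. A response to CINP depletion also stays open and untested.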
